A study of Mus musculus with 2 samples.

How the data were processed

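RNA was sequenced from 2 tumours grown from Hepa1-6, a mouse hepatocellular carcinoma cell line, in C57BL/6 mice. Before injection the cells had been transduced with a lentivirus carrying either IRF8 or no insert (vector), together with a GFP and puromycin resistance cassette, per the labels. Each cell population was injected on its own side of the same mouse, and RNA was taken from the whole tumour with Trizol. Libraries were made from 3 μg of total RNA with a NEBNext Ultra RNA kit, per the labels' protocols. The kit as named does not mark strand, so reads from a gene and from an overlapping antisense gene cannot be separated. The host and the tumour cells are both mouse, so reads from the 2 sources cannot be separated either.

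The deposited table holds raw counts per gene for both libraries, with gene symbols, biotypes and coordinates. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 genome build. How reads that map to several places were treated is not given in the sources used here. Genes with near-identical copies are therefore uncertain. They include immunoglobulin and T cell receptor segments, the alpha globins, the mitochondrial genes with nuclear copies, and genes with many processed pseudogenes such as Gapdh. Gene length and coordinate columns of the deposited table served as annotation. Of its 54532 gene identifiers, 54495 were also in GENCODE M21, and 53585 had the same start and end there. Coordinates below are those of the deposited table (mm10, counted from 1).

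The labels give 1 library per group. The difference between the libraries therefore has no replicate check, and no p-value, standard error or test-based count of genes was computed. All sizes below compare these 2 libraries, not the 2 conditions. The total was 20223649 counts in the vector-labelled library and 17316607 in the IRF8-labelled library. A count of 0 was taken as a level of up to 0.150 CPM in the first and 0.171 CPM in the second (3 counts per library).

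Scaling factors came from TMM in edgeR 4.0.16 (R 4.3.3). The log2 ratio of a gene, IRF8-labelled over vector-labelled, was computed as in edgeR's log CPM with a prior count of 2. A gene was called measured at a mean of at least 1 CPM, which left 14775 genes. Counting intervals are 95% Clopper-Pearson intervals of the IRF8-labelled share of a gene's counts, converted to a ratio with the effective library sizes. They cover counting error only, since they rest on the split of 2 counts. PCR copies were not marked, so they may be too narrow even for that. A gene was counted as higher or lower when its log2 ratio was at least 1 in size and its interval excluded 0. For a gene with 0 counts in one library, the fold was computed against 3 counts in that library. The end of its counting interval nearer to no difference is given beside it. Folds of named genes come from scaled counts without the prior count.

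Genes were named by a rule written before the data were examined. It took Irf8 and its family, and the 12 largest and 12 smallest log2 ratios among protein-coding genes with a mean of at least 5 CPM. It added up to 4 members of each gene list with the largest ratios in either direction, 11 genes fixed by name, and up to 4 of the most abundant genes of any chromosome or window that stood apart. Other genes are marked where they appear. The 41 gene lists (cell type markers, pathways, gene families and signs of RNA quality) were also fixed before the data were examined. For a list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists under the 1st or over the 99th percentile are described as standing apart. Among 39 placed lists, about 0.39 would lie past each limit by chance if the genes of a list varied independently. The random lists were drawn gene by gene. Genes of a real list can vary together, and lists share members, so more lists can pass between any 2 tumours. The percentile describes these 2 libraries. Chromosome medians, and medians of 50 consecutive genes, were compared with 1000 shuffles of gene order.

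The steps were tested on simulated data for this comparison of 14742 genes. Poisson counts were drawn from the pooled profile of both libraries at their real totals. Of the genes, 200 were set to differ, and 194 of these were measured. The size rule recovered 50 of 50 genes set 4-fold higher and 50 of 50 set 2.5-fold higher. It recovered 48 of 50 set to 0.25 of the vector level and 44 of 50 set to 0.4. Of 14548 genes with no set difference, 22 met the rule, and 95.4% of their intervals held 0. Of 300 random lists without a shift, 2% lay past a limit, which limits at the 1st and 99th percentile give by design. All of 50 lists shifted by 0.3 on the log2 scale were recovered. Both kinds of list were drawn at random, so lists of genes that vary together were not tested. The simulated counts held no variation between tumours, so these rates cover counting error only. In the real data the 99th percentile of matched random lists was above 0.3 for several lists, most of them of immune cells. It was 0.31 for T cells, 0.35 for cytotoxic and natural killer genes, 0.45 for B and plasma cells and 0.52 for neutrophils. It reached 0.62, for mast cells, and a shift of 0.3 would not pass in any of these lists.

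The alternatives planned before the data were examined were DESeq2 1.42.0 median-of-ratios scaling, library totals, TMM without the 20 most abundant genes, no filter on expression, a mean of at least 5 CPM, prior counts of 0.5 and 5, protein-coding genes only, the vector-labelled library thinned to the depth of the other, a log2 threshold of 2, list means, and random lists without matching. A pair of gene exclusions was added after the data were seen. Other computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. The list genes absent from the table under the symbol used, 5 in number, were left out. A few named genes are not reported here, and they stay in the list counts and medians.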

Results

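The data are gene counts from 2 tumours, 1 per group, grown from Hepa1-6 cells on either side of the same C57BL/6 mouse. One tumour is labelled as grown from cells carrying an empty vector and the other from cells carrying an IRF8 overexpression construct. IRF8 (interferon regulatory factor 8) is a transcription factor known for its part in the development of myeloid and B cells and in the response to interferon gamma. The comparison asks how the tumour transcriptome differs when the injected cancer cells carry the IRF8 construct. Total counts were 20223649 in the library labelled vector and 17316607 in the library labelled IRF8-overexpression, and 24409 and 24035 of the 54532 listed genes had at least 1 count. After scaling, the median log2 ratio of the 14775 measured genes was -0.0012, and 86.1% of them lay within 1.5-fold between the libraries.

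Irf8 itself was lower in the library labelled IRF8-overexpression. The gene (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694, plus strand) had 4178 counts in the library labelled vector and 2578 in the one labelled IRF8-overexpression. These are 209.5 CPM (95% exact Poisson interval 203.2 to 215.9) and 146.8 CPM (141.2 to 152.6). The log2 ratio was -0.51 (95% counting interval -0.58 to -0.44), a level 29.9% lower. The targeted gene therefore goes against the labels, and the libraries are called the IRF8-labelled and the vector-labelled library from here on. Every direction below rests on these labels. Gene counts do not separate reads of a transgene from reads of the mouse gene, and GFP and puromycin resistance sequences were not analysed here. Among other genes of the family, Irf1 had a log2 ratio of -0.24 (-0.29 to -0.20) and Irf5 of 0.23 (0.11 to 0.35). The intervals of Irf2, Irf4, Irf7 and Irf9 held 0, and Irf3 was at 0.15 (0.021 to 0.29).

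**Figure D1:**
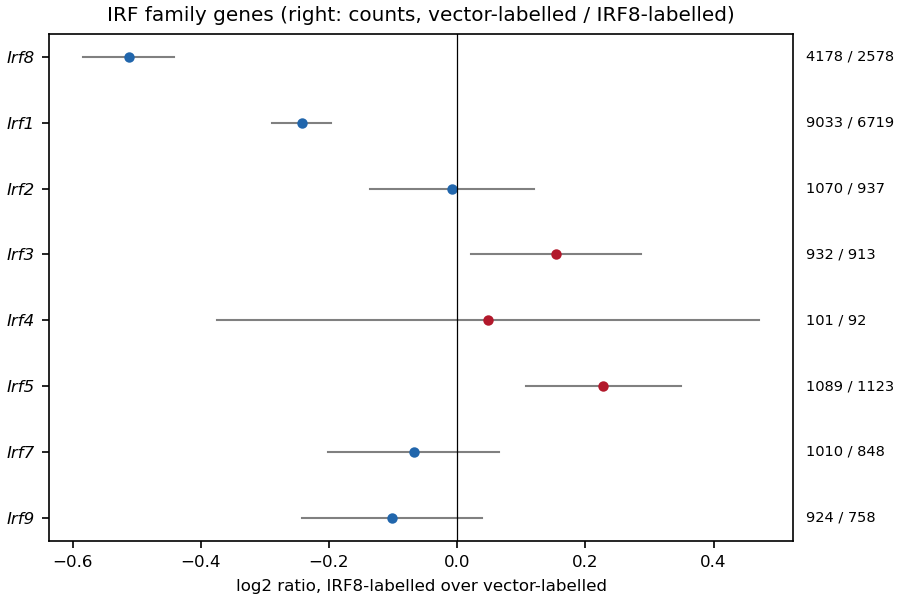
Log2 ratio (IRF8-labelled over vector-labelled library) of 8 IRF family genes, with 95% counting intervals as bars and the counts of both libraries at the right; 1 library per group. Irf8 lies at -0.51, the lowest of the genes drawn, with 4178 and 2578 counts.

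Genes of secreted liver proteins and mast cell proteases were far lower in the IRF8-labelled library. Interferon gamma response genes, many chemokines and genes of cell division were lower by smaller margins. Genes of skeletal muscle, adipocytes and antibody-producing cells were far higher. By the size rule, 383 genes were at least 2-fold higher and 410 at least 2-fold lower in the IRF8-labelled library. Without filtering on expression these counts were 814 and 719, and with a mean of at least 5 CPM they were 119 and 179. Among 39 gene lists placed against matched random lists, 7 stood above and 14 below. With 1 library per group, none of these differences has a replicate check.

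The gene with the largest ratio was Tex101, known as a surface protein of germ cells (ENSMUSG00000062773, chromosome 7, 24668007 to 24676675, minus strand). It had 0 counts in the vector-labelled and 2042 in the IRF8-labelled library. Its level was 773-fold higher against 3 counts, with a counting interval beginning at 628-fold. The 23 measured genes starting within 500 kb of it had a median log2 ratio of 0.10. Prr19, on the same chromosome at 25301411 to 25304132, had 5 and 238 counts (54.1-fold higher, 22.9 to 168.1). The other 10 of the 12 largest ratios belonged to Car3, an enzyme abundant in fat and muscle, and to 9 muscle genes described below.

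The smallest ratios belonged mainly to genes of hepatocyte secretion. Fga, the fibrinogen alpha chain (ENSMUSG00000028001, chromosome 3, 83026076 to 83033627, plus strand), had 4992 counts in the vector-labelled and 4 in the IRF8-labelled library, 1099-fold lower (429 to 4033). Ahsg, which encodes fetuin-A, had 2187 and 7 counts (275-fold lower, 133.2 to 685). Kng1 (kininogen) had 668 and 1 counts (588-fold lower, 105.2 to 23260). Itih3 had 258 and 0 counts, 75.7-fold lower against 3 counts, with a counting interval beginning at 61.1-fold. Apoh had 274 and 1 counts (241-fold lower, 42.9 to 9560), and plasminogen (Plg) had 204 and 2 (89.8-fold lower, 24.5 to 746). Fgg was 69.9-fold lower (45.1 to 115), the fatty acid binding protein gene Fabp1 68.9-fold (26.6 to 254), the protease inhibitor gene Pzp 60.0-fold (46.8 to 78.2) and Apoa2 27.9-fold (log2 interval -5.88 to -3.90). Reg3g, an antimicrobial lectin, had 258 and 3 counts (75.7-fold lower, 25.6 to 370), and the carboxylesterase gene Ces2e had 263 and 13 (17.8-fold lower, 10.2 to 33.9).

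Across the hepatocyte list, 12 of 22 measured genes were at least 2-fold lower and 2 were at least 2-fold higher in the IRF8-labelled library. The median log2 ratio was -1.53, below each of the 10000 matched random lists, whose 1st percentile was at -0.17. Alb had 74718 and 32892 counts (95% interval of the log2 ratio -1.02 to -0.98), and Apoa1, the main protein of high density lipoprotein, was at -2.28 (-2.44 to -2.13). The gene of the hepatocyte transcription factor Hnf4a had a log2 ratio of 0.06 (-0.02 to 0.13), and Apob was at 0.10 (0.053 to 0.15). The 2 members that were higher were Pck1, a gluconeogenic enzyme also abundant in fat, with 1 and 101 counts (log2 interval 4.33 to 12.2), and Cyp2e1 with 6 and 61. Apoa1, Hnf4a, Apob, Pck1 and Cyp2e1 were chosen after their values were seen.

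Acute phase and complement genes were lower as well, with 7 of 11 measured members at least 2-fold lower and a list median of -1.83. Apcs had 60 and 0 counts, 17.6-fold lower against 3 counts, with a counting interval beginning at 13.9-fold. With Apcs at the 17.6-fold value the median was also -1.83. Haptoglobin (Hp) was 7.18-fold lower (6.18 to 8.39), lipocalin 2 (Lcn2) 7.55-fold (5.69 to 10.2) and hemopexin (Hpx) 4.54-fold (4.18 to 4.92). Fetal liver and progenitor genes had no common direction, with a list median of -0.14 at percentile 8.07 of random lists. Alpha-fetoprotein (Afp), the usual serum marker of hepatocellular carcinoma, had 51825 and 16458 counts, 2.77-fold lower (2.72 to 2.82). The oncofetal proteoglycan gene Gpc3 was 11.8-fold lower (10.3 to 13.5) and Lin28b 2.96-fold lower (1.48 to 6.43). The imprinted RNA H19 was 2.35-fold higher (1.92 to 2.90).

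**Figure D2:**
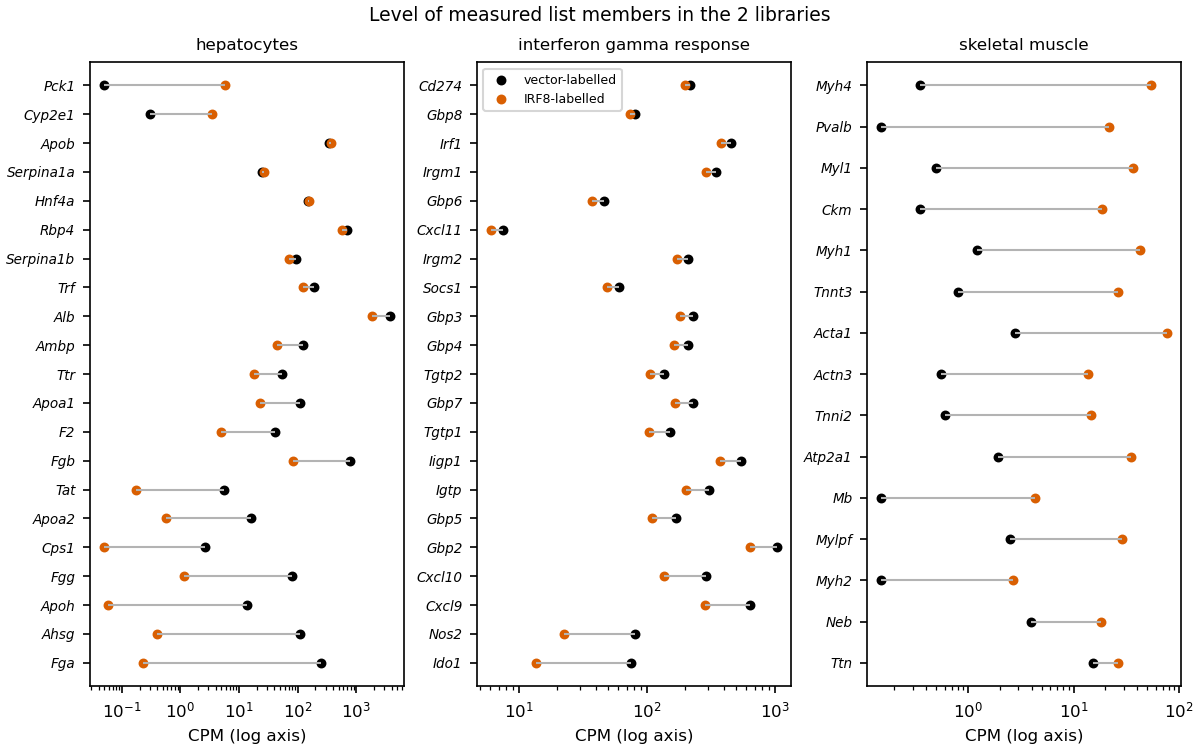
CPM (log axis) of measured members of the hepatocyte, interferon gamma response and skeletal muscle lists in the vector-labelled (black) and IRF8-labelled (orange) library; each point is 1 library, and counts of 0 are drawn at 0.05 CPM. Hepatocyte genes spread from Fga (4992 and 4 counts) to Pck1 (1 and 101 counts), 20 of 21 interferon gamma genes have counting intervals below 0, and all 15 muscle genes lie higher in the IRF8-labelled library.

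Genes of the interferon gamma response were lower in the IRF8-labelled library, with counting intervals below 0 for 20 of 21 measured members and a median log2 ratio of -0.36, below each matched random list. The tryptophan-degrading enzyme gene Ido1 was 5.45-fold lower (4.76 to 6.27) and inducible nitric oxide synthase, Nos2, 3.60-fold (3.22 to 4.03). The T cell-attracting chemokine genes Cxcl9 and Cxcl10 were 2.26-fold (2.18 to 2.33) and 2.14-fold (2.04 to 2.24) lower. The type I interferon list did not stand apart, with a median of -0.051 at percentile 23.4. It had intervals below 0 for 12 of 26 measured members and above 0 for none. Its members with the largest ratios were Oasl1 at -0.71 (-0.83 to -0.59), Usp18 at -0.62 (-0.75 to -0.49), Rsad2 at -0.50 (-0.81 to -0.21) and Cmpk2 at -0.40 (-0.72 to -0.09).

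Antigen presentation differed little between the libraries. The MHC class I list had a median of -0.08 (percentile 33.1), with intervals below 0 for 13 of 19 genes and above 0 for 1. Its members with the largest ratios were Tap1 at -0.38 (-0.43 to -0.33), Psmb9 at -0.35 (-0.42 to -0.28), Psmb8 at -0.31 (-0.37 to -0.25) and H2-T23 at -0.28 (-0.33 to -0.24). The MHC class II list had a median of -0.013 (percentile 64.5). Its transactivator gene Ciita was at -0.39 (-0.49 to -0.29) and the peptidase gene Ctss at -0.37 (-0.41 to -0.33), while H2-Ob was 2.48-fold higher (1.55 to 4.07) from 27 and 59 counts. Checkpoint ligands had a median of 0.16 (percentile 97.9), and with the vector-labelled library thinned they passed the limit (0.18, percentile 99.16). Cd274, which encodes PD-L1, was at -0.12 (-0.19 to -0.06), Lgals9 at -0.57 (-0.65 to -0.48), Fgl1 at -1.08 (-1.24 to -0.92) and Vtcn1 at 0.98 (0.72 to 1.27).

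Chemokine genes were lower as a family, with 7 of 30 measured members at least 2-fold lower, 1 at least 2-fold higher and a median of -0.38. Ccl20, the ligand of Ccr6 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167, plus strand), had 188 and 40 counts and was 4.14-fold lower (2.93 to 5.97). Ccr6 had 1 count in the vector-labelled and 4 in the IRF8-labelled library, a ratio whose interval runs from 0.45 to 224. The eosinophil attractant gene Ccl11 was 6.26-fold lower (3.81 to 10.9), Ppbp 3.63-fold (2.32 to 5.86) and Ccl8 2.89-fold (2.63 to 3.18). Chemokine receptors did not stand apart (median -0.0081, percentile 39.5). Among them Ccr7, which guides cells to lymph nodes, was 3.32-fold higher (2.82 to 3.93) and Cx3cr1 1.73-fold higher (log2 interval 0.59 to 0.997), with Cxcr2 at -0.57 (-1.16 to -0.029) and Ackr3 at -0.55 (-0.87 to -0.25). Cytokines and growth factors had a median of 0.02 (percentile 60.2), with Tnfsf10 (TRAIL) 2.09-fold lower (1.85 to 2.36) and Il33 1.49-fold lower (1.33 to 1.66). Csf2 had a log2 ratio of 0.65 (0.08 to 1.28) and Tgfb2 of 0.53 (0.12 to 0.97).

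Most T cell and cytotoxic genes were lower in the IRF8-labelled library, by less than 2-fold for most members. The T cell list had a median of -0.32 at percentile 0.02, with intervals below 0 for 11 of 18 genes and above 0 for none. Cd28 was 2.26-fold lower (1.72 to 3.00), Lck 1.75-fold (1.45 to 2.11), Cd2 1.69-fold (1.32 to 2.17), Cd8b1 1.69-fold (1.28 to 2.23) and Cd8a 1.22-fold (1.08 to 1.39). Several defining T cell genes, chosen after their values were seen, had intervals that held 0, with Cd3e at 0.0056, Trac at -0.02, Cd4 at -0.06 and Trbc1 at 0.19, and the summed T cell receptor constant genes had a scaled ratio of 0.97. The cytotoxic and natural killer list had a median of -0.42 at percentile 0.05. Ifng had 88 and 35 counts (2.21-fold lower, 1.48 to 3.38), granzyme B (Gzmb) was 2.08-fold lower (1.78 to 2.43), perforin (Prf1) 1.66-fold (1.38 to 1.99) and Gzma 1.51-fold (1.08 to 2.14). With list means in place of medians these 2 lists were at percentiles 1 and 1.69, which does not pass the limit. Regulatory T cell genes as a list did not stand apart (median -0.09, percentile 21.4), and Foxp3 had 67 and 28 counts (2.11-fold lower, 1.34 to 3.40). Il2ra was at -0.50 (-0.99 to -0.04), Ctla4 at -0.64 (-1.02 to -0.29) and Ikzf2 at 0.24 (-0.09 to 0.57). The checkpoint receptor list had a median of -0.18 (percentile 4.14), with Pdcd1, which encodes PD-1, at -0.29 (-0.54 to -0.04) and Entpd1 at -0.45 (-0.58 to -0.32). The intervals of Btla and Cd160 in that list held 0.

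B cell and plasma cell genes went the other way. All 8 measured members had counting intervals above 0, 6 were at least 2-fold higher and the median was 1.98, above each matched random list. The list has 14 genes, and 4 of the 8 measured were at 1 CPM or more in the vector-labelled library. With protein-coding genes only, the median was 1.57 and too few members were left to be placed. The kappa constant gene Igkc had 476 and 1965 counts (4.69-fold higher, 4.24 to 5.20). Iglc2 had 1 and 238 counts (270-fold higher, 48.1 to 10720), Iglc1 was 12.1-fold higher (5.86 to 28.9) and the B cell kinase gene Blk 5.03-fold higher (2.17 to 13.5). The lambda constant genes are near-identical copies, so the split of reads between them is uncertain.

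Macrophage genes as a list did not stand apart (median -0.047, percentile 41.0). Adgre1, which encodes F4/80, was at -0.43 (-0.58 to -0.28), the mannose receptor gene Mrc1 at -0.41 (-0.52 to -0.30), Cd14 at -0.47 (-0.65 to -0.29) and Ms4a7 at 0.33 (0.13 to 0.52). Markers of alternative activation stood below random lists with a median of -0.45. Chil3 was 4.60-fold lower (3.38 to 6.38), Retnla 2.75-fold (2.21 to 3.45), arginase 1 (Arg1) 1.53-fold (1.43 to 1.64) and Ccl24 1.52-fold (1.44 to 1.61). The monocyte list was at -0.19 (percentile 5.88), with F13a1 at -0.88 (-1.18 to -0.61) and Plac8 at -0.31 (-0.44 to -0.18). Myeloid genes associated with IRF8 and the phagocyte oxidase were at -0.029 (percentile 52.0), where Ncf4 at 0.58 (0.39 to 0.77) and Ncf1 at 0.46 (0.30 to 0.61) stood opposite Cybb at -0.32 (-0.41 to -0.24). Dendritic cell genes had a median of 0.14 (percentile 90.6), led by Ccr7, with Zbtb46 at 0.51 (0.30 to 0.73), Ccl22 at 0.51 (0.24 to 0.78) and Cd83 at 0.45 (0.32 to 0.58).

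Mast cell genes were lower, with 5 of 6 measured members at least 2-fold lower and a median of -1.89. Carboxypeptidase A3 (Cpa3) was 4.56-fold lower (2.87 to 7.56), the chymase gene Cma1 4.34-fold (2.92 to 6.66), Tpsb2 3.84-fold (2.86 to 5.22) and Mcpt4 3.79-fold (2.70 to 5.41). Neutrophil and myeloid suppressor genes had a median of -0.40 at percentile 0.55, from Clec4e (4.60-fold lower, 2.76 to 8.09), Hdc (2.98-fold lower, 1.85 to 4.98) and Clec4d (2.40-fold lower, 1.67 to 3.53). Ly6g was 1.64-fold higher (1.07 to 2.56). This list did not keep its direction among genes with a mean of at least 5 CPM, where its median was 0.0010, and it was inside the limit by list means (percentile 2.3) and with the vector-labelled library thinned (1.19).

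Skeletal muscle genes were higher in the IRF8-labelled library in all 15 measured members, 14 of them at least 2-fold, with a median of 4.41. The whole list held 624 counts in the vector-labelled library and 7414 in the IRF8-labelled library. These are 0.0031% and 0.043% of all counts, a small part of each. Host and tumour reads were not separated, so the tissue that these muscle transcripts, and the adipocyte transcripts below, came from was not tested. The myosin heavy chain gene Myh4 (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446, plus strand) had 7 and 955 counts (155-fold higher, 74.9 to 387). Parvalbumin (Pvalb) had 3 and 383 (145-fold higher, 49.3 to 706). Myl1 was 73.2-fold higher (39.5 to 153.3), creatine kinase (Ckm) 53.4-fold (25.6 to 134), Myh1 35.6-fold (23.7 to 55.9), Tnnt3 33.0-fold (20.1 to 58.1), Acta1 27.9-fold (21.3 to 37.3), Actn3 25.1-fold (13.8 to 50.9) and Tnni2 24.3-fold (13.7 to 47.7). Adipocyte genes stood above random lists with a median of 2.86, and 7 of 8 were at least 2-fold higher. Car3 was 21.3-fold higher (log2 interval 3.91 to 4.97) and adipsin (Cfd) 15.4-fold (10.5 to 23.5). Plin1 had 2 and 38 counts (21.6-fold higher, 5.58 to 185), and adiponectin (Adipoq) had 3 and 39 (14.8-fold higher, 4.70 to 74.7). The remaining member, the lipoprotein lipase gene Lpl, is the most abundant of the list and was lower, with 6107 and 2692 counts (log2 interval -1.06 to -0.93), and the summed level of the list was 340.1 and 281.3 CPM. Lpl was chosen after its values were seen. In the vector-labelled library 6 of the 15 muscle genes and 4 of the 8 adipocyte genes were at 1 CPM or more. Without muscle, adipocyte and B cell list members and immunoglobulin genes, an exclusion chosen after the data were seen, 343 genes were at least 2-fold higher and 409 at least 2-fold lower.

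Matrix and vascular genes differed less. The fibroblast list had a median of 0.19 at percentile 99.9, with Pdgfrb at 0.79 (0.71 to 0.87), Thy1 at 0.74 (0.67 to 0.82), Col6a3 at 0.64 (0.58 to 0.69) and Mfap5 at -1.36 (-1.71 to -1.05). Genes of epithelial-mesenchymal transition had a median of 0.16 at percentile 99.4, and they went both ways, with Snai2 1.99-fold higher (1.30 to 3.08), Twist1 1.72-fold higher (1.29 to 2.29), Mmp9 2.42-fold lower (2.29 to 2.56) and Lox 1.62-fold lower (1.41 to 1.86). Hypoxia and glycolysis genes had a median of 0.18 at percentile 99.97, with P4ha2 at 0.67 (0.57 to 0.77), Ndrg1 at 0.50 (0.45 to 0.55), P4ha1 at 0.41 (0.34 to 0.47) and Adm at 0.41 (0.0013 to 0.85). Against random lists without matching on expression, these 3 lists were at percentiles 98.6, 94.9 and 98.5, inside the limit. By list means the fibroblast list was at percentile 94.95 and the epithelial-mesenchymal list at 74.3, and the latter was also inside at a mean of at least 5 CPM (91.8) and without chromosomes 9, 15 and 16 (median 0.064, percentile 94.94), an exclusion chosen after the data were seen. The endothelial list was at 0.23 (percentile 98.5), where Egfl7 at 0.65 (0.42 to 0.89), Emcn at 0.65 (0.30 to 1.02) and Cldn5 at 0.54 (0.17 to 0.94) were its largest ratios above 0. Tek had a log2 ratio of -0.57 with an interval holding 0.

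Genes of cell division were lower in the IRF8-labelled library by a narrow margin and with little spread. All 20 genes of the G2 and mitosis list had intervals below 0, with a median of -0.39, and none reached 2-fold. Cyclin B1 (Ccnb1) was at -0.64 (-0.76 to -0.52), the spindle motor gene Kif11 at -0.57 (-0.66 to -0.47), Aurka at -0.53 (-0.68 to -0.38) and Cdc20 at -0.51 (-0.65 to -0.37). DNA replication genes had a median of -0.35, with 16 of 20 intervals below 0. By list means this list was at percentile 1.03, which does not pass the limit. Ribonucleotide reductase subunit Rrm2 was at -0.62 (-0.76 to -0.48), Ccne2 at -0.53 (-0.75 to -0.31), Mcm5 at -0.50 (-0.63 to -0.38) and Cdc6 at -0.50 (-0.72 to -0.28). The p53 and apoptosis list did not stand apart (median -0.09, percentile 17.3), with Fas at -0.64 (-0.86 to -0.43), Sesn2 at -0.37 (-0.60 to -0.15), Gadd45a at 0.54 (0.26 to 0.83) and Bcl2 at 0.52 (0.34 to 0.71).

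Lipid synthesis genes were lower too. In the cholesterol synthesis list 15 of 16 genes had intervals below 0 and the median was -0.38, with Idi1 1.78-fold lower (1.51 to 2.10), Dhcr7 1.71-fold (1.51 to 1.95) and squalene epoxidase (Sqle) 1.58-fold (1.51 to 1.65). Fatty acid synthesis genes had a median of -0.25 at percentile 0.18, with Gpam at -0.79 (-0.91 to -0.67), stearoyl-CoA desaturase Scd1 at -0.70 (-0.76 to -0.63) and Elovl6 at -0.66 (-0.81 to -0.51). Thrsp, a lipogenic gene abundant in fat, was 16.2-fold higher (5.99 to 61.4), and with it the list's mean was -0.0049, at percentile 61.4. The unfolded protein response list was at -0.16 (percentile 5.03), and its mean of -0.37 was past the limit at percentile 0.7, with the stress-induced genes Chac1 4.79-fold (2.79 to 8.74) and Trib3 4.29-fold lower (3.43 to 5.41), Asns at -0.55 (-0.64 to -0.47) and Ddit3 at -0.34 (-0.53 to -0.15).

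Of the lists read as signs of RNA quality or handling, mitochondrially encoded genes were higher in all 12 measured members, with a median of 0.38. The largest ratios were of mt-Atp6 (3.38-fold, 3.20 to 3.58), mt-Co3 (2.18-fold, 2.01 to 2.37) and mt-Co2 (1.90-fold, 1.77 to 2.04), which have near-identical nuclear copies, and mt-Nd3 was at 0.58 (0.12 to 1.08). Ribosomal protein genes had a median of -0.19 at percentile 0.51, with intervals below 0 for 27 of 28, led by Rpl8 at -0.35 (-0.37 to -0.32), Rpl18 at -0.34 (-0.38 to -0.31), Rpl32 at -0.32 (-0.35 to -0.29) and Rps3 at -0.32 (-0.35 to -0.30). By list means the ribosomal list was at percentile 2.41, which does not pass the limit. Immediate early and heat shock genes were at 0.14 (percentile 97.2), with Hspb1 3.05-fold higher (2.20 to 4.30), Hspa1b 1.61-fold (1.16 to 2.24), Dusp1 1.48-fold (1.38 to 1.57) and Junb at a log2 ratio of 0.59 (0.55 to 0.63). Keratinocyte and erythroid lists had 4 and 3 measured members and were not placed. With no filter on expression the keratinocyte list was placed below the limit (median -0.56, percentile 0.365), against a median of 0.19 for the 4 measured genes. The unfiltered list includes genes with hardly any counts, whose ratios are set by the prior count, so that placement says little. Among the measured keratinocyte genes, Krt14 was 2.49-fold higher (1.91 to 3.25) and Krt5 1.84-fold lower (1.20 to 2.88). The intervals of Krt10, Sfn and the 3 globin genes held 0.

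**Figure D3:**
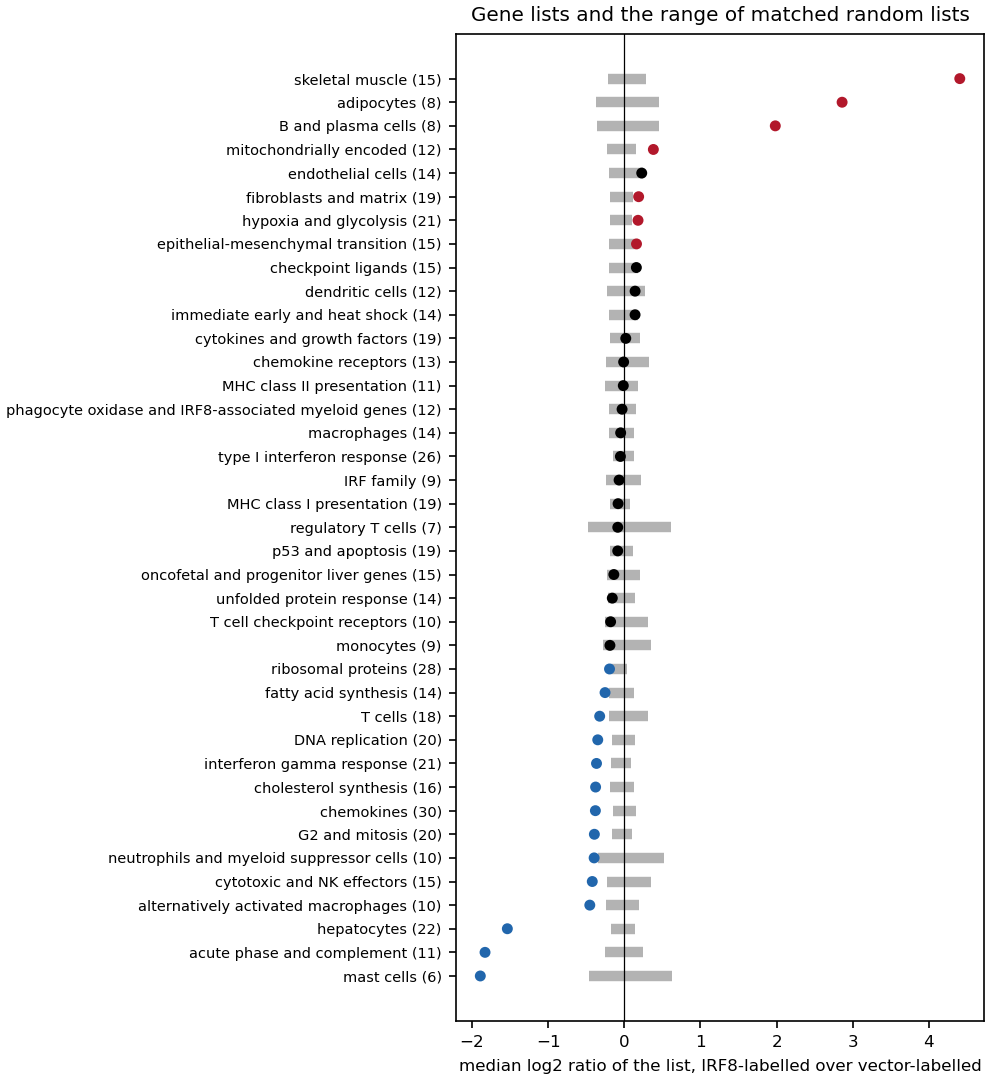
Median log2 ratio (IRF8-labelled over vector-labelled library) of each gene list with at least 5 measured members, given in brackets, as a point; grey bars span the 1st to 99th percentile of 10000 matched random lists. Red points lie above the 99th percentile (7 lists, from skeletal muscle at 4.41) and blue points below the 1st (14 lists, down to mast cells at -1.89).

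Genes of chromosomes 9 and 16 were higher along the whole chromosome and genes of chromosome 15 lower. The median log2 ratio was 0.19 over 794 genes of chromosome 9 (95% bootstrap interval over genes 0.17 to 0.21), 0.13 over 465 genes of chromosome 16 (0.11 to 0.17) and -0.12 over 584 genes of chromosome 15 (-0.14 to -0.09). In 1000 shuffles of gene order, medians of the 20 chromosomes ran from -0.057 to 0.052. On chromosome 9, 77.3% of genes had a ratio above 0, and each of its 15 windows of 50 genes had a median between 0.11 and 0.28. All 9 windows of chromosome 16 lay above 0 and all 11 of chromosome 15 below. Chromosomes 18 (-0.057) and X (-0.065) lay just past the shuffles, and both lay inside them (-0.031 and -0.037) once trends on GC content, gene length and expression were removed. Among the most abundant genes of chromosome 18, Cd74 was at -0.013 (-0.03 to 0.0052), Rps14 at -0.19 (-0.21 to -0.16), Atp5a1 at -0.30 (-0.33 to -0.27) and Rpl17 at -0.30 (-0.34 to -0.27). On the X chromosome Rpl10 was at -0.20 (-0.22 to -0.17), Rps4x at -0.20 (-0.22 to -0.17), Xist at -0.18 (-0.21 to -0.16) and Flna at -0.14 (-0.17 to -0.11). Of 287 windows, 1 lay past the highest shuffled window median of 0.26, on chromosome 9 from 111271929 to 120132369, where the most abundant genes were Rpsa, Pdcd6ip at 0.19 (0.14 to 0.25), Stt3b at 0.15 (0.09 to 0.22) and Tgfbr2 at 0.14 (0.07 to 0.21). Of the 4 most abundant genes of chromosome 9, Pkm was at 0.18 (0.16 to 0.20), near the chromosome median, and the translation genes Eef1a1 at -0.26 (-0.28 to -0.25), Rpl4 at -0.034 (-0.056 to -0.012) and Rpsa at -0.032 (-0.054 to -0.0089) lay below 0. On chromosome 16 App was at 0.14 (0.11 to 0.18), Son at 0.39 (0.35 to 0.43) and Col8a1 at 0.44 (0.40 to 0.49), and Eif4g1 was at 0.01 (-0.029 to 0.049). On chromosome 15 Pabpc1 was at -0.19 (-0.21 to -0.17), Rpl8 at -0.35 and Rpl30 at -0.29 (-0.32 to -0.26), and Enpp2 was at 0.04 (0.02 to 0.07).

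**Figure D4:**
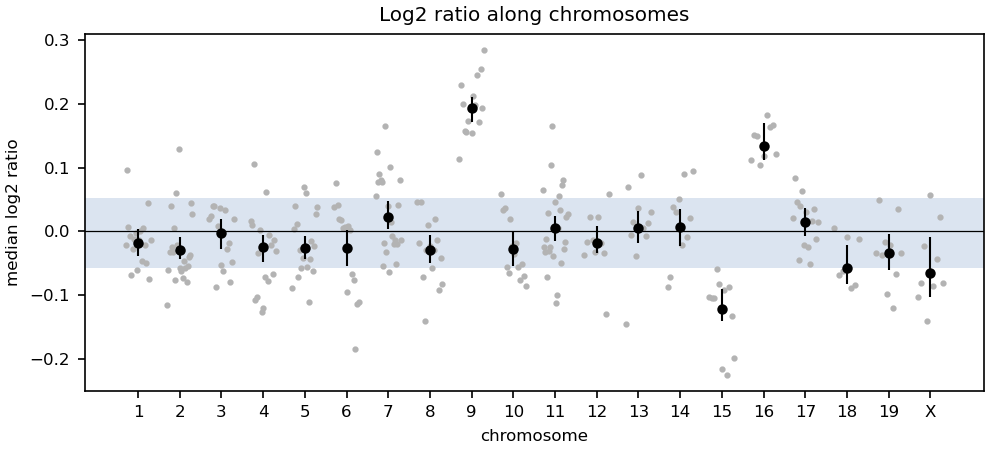
Median log2 ratio (IRF8-labelled over vector-labelled library) of measured genes on each chromosome (black, with 95% bootstrap intervals over genes) and of consecutive windows of 50 genes (grey). The shaded band is the range of chromosome medians in 1000 shuffles of gene order, -0.057 to 0.052, and chromosomes 9 (0.19), 16 (0.13) and 15 (-0.12) lie outside it, with 18 (-0.057) and X (-0.065) just past its lower edge.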

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

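The gene exclusions were chosen after the data were seen, and the other alternatives were planned. Irf8 was lower in the IRF8-labelled library under every scaling, filter, prior count and depth tried, and its log2 ratio lay inside its counting interval each time. Counts of genes at least 2-fold higher and lower were 383 and 410. They became 814 and 719 with no filter, 119 and 179 at a mean of at least 5 CPM, and 86 and 116 at a log2 threshold of 2, where the number of genes tested or the threshold itself sets the change. Under the other alternatives they stayed within 1.5 times. No scaling moved the median of all genes by over 0.1: it was -0.0012, and 0.039 with library totals. That scaling moved the largest chromosome offset, of chromosome 9, from 0.19 to 0.23. Lists below the 1st percentile numbered 14, and 9 by list means. Lists above the 99th percentile numbered 7. They numbered 4 against random lists without matching on expression, and 4 without muscle, adipocyte and B cell genes, which removes 3 of the lists. The median of the neutrophil and myeloid suppressor list reversed to 0.0010 at a mean of at least 5 CPM, with too few members left to be placed. Except for the change made by construction, the cause was not tested. Of 1984 ratios of named genes under alternatives, 13 left their counting interval and 0 of those past the size rule changed sign. Of 530 list values, 20 changed their side of a limit or whether they could be placed. In addition, 1 value of a list past a limit reversed and could not be placed. Median and mean differed in sign in 4 lists near 0 and inside the limits (MHC class II, phagocyte oxidase, chemokine receptors and cytokines). Depth limits genes with few counts in one library, such as Kng1 and Apoh, whose folds have intervals spanning over 100-fold. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library, although both tumours are described as grown in the same mouse.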

Other observations

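The tests of myeloid genes, of interferon gamma genes, of swapped labels, of tumour cell share, of host liver and of chromosome windows, and the scan of gene families by symbol, were chosen after the results they bear on had been seen. The correction of the chromosome 9 offset for GC content, length and expression was written before its value was known.

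Summed over genes, immunoglobulin variable segments were higher in the IRF8-labelled library, as were most constant genes. Over 218 listed segments the counts summed to 304 in the vector-labelled and 1219 in the IRF8-labelled library, a scaled ratio of 4.56, and segments with at least 10 counts numbered 7 and 35. Among constant genes, Ighg2c had 176 and 1494 counts (log2 ratio 3.25, 3.04 to 3.50), Ighg2b 263 and 790 (1.76, 1.57 to 1.98), Ighg1 272 and 698 (1.54, 1.34 to 1.75) and Igha 198 and 227 (0.38, 0.10 to 0.66). Ighg3 went the other way with 22 and 3 counts (-2.12, -5.07 to -0.96), as did the variable segment Igkv5-39 with 39 and 10 (-1.61, -2.95 to -0.75), and Ighd had 14 in each. T cell receptor variable segments had 411 and 318 counts, a scaled ratio of 0.88, and Trdv4 alone supplied 193 and 191 of them. T cell receptor constant genes had 840 and 719 counts, a ratio of 0.97. These genes were chosen after their values were seen, and the split of reads between similar segments is uncertain.

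Among 420 groups of genes sharing a symbol stem, 23 stood below and 14 above matched random lists. About 1% would lie past each limit by chance if genes varied independently, and some groups share genes with the lists above. Aldo-keto reductases of the Akr1c group were lower in the IRF8-labelled library (7 genes, median -0.99), as were Serpina protease inhibitors (10 genes, -0.77) and guanylate binding proteins (10 genes, -0.35). Serpinb inhibitors were higher by median (12 genes, median 0.66, 4 of them at least 2-fold), as were zinc finger genes named Zfp (322 genes, 0.14). Adamts metalloproteases (11 genes, 0.52) had 1 gene at least 2-fold higher and 1 at least 2-fold lower. Insulin-like growth factor binding proteins (6 genes, 0.46) had 0 at least 2-fold higher and 1 at least 2-fold lower. By the transcription factor families of the deposited annotation, C2H2 zinc fingers (426 genes) had a median of 0.13, and the IRF family did not stand apart (-0.068).

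Irf8 was lower in the IRF8-labelled library by 29.9%, against its label. If its reads came only from host myeloid cells that were fewer, with transgene reads not counted, then 37 macrophage, dendritic cell and MHC class II genes would be lower by as much. Their median was -0.013 with a robust SD of 0.27, and 0 of them lay at or below Irf8. The macrophage list alone was at -0.047, with 3 intervals above 0 and 6 below. Its members Cd14 (-0.47), Adgre1 (-0.43) and Mrc1 (-0.41) had intervals that overlapped that of Irf8. As a set, these 37 genes argue against fewer macrophages and dendritic cells as the whole cause. The set is not limited to genes of these cells alone, and a fall in part of the macrophages stays open. The monocyte, alternative activation and neutrophil lists, with medians of -0.19, -0.45 and -0.40, were not in this test. Fewer cells of those kinds therefore stay open. Lower interferon gamma signalling is a candidate explanation, since Irf8 is induced by it, and 9 of the 21 genes of that list had ratios at or below that of Irf8. The list was known to be lower before this comparison was set, so the comparison could not count against the explanation. Swapped labels stay open: Irf8 was lower than the myeloid median by a log2 difference of -0.50, but with 1 library per group and no second marker of the construct a swap cannot be told apart from loss of the transgene or from a transgene sequence that was not counted. An effect of the IRF8 construct itself on the tumour also stays open and untested.

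Hepatocyte genes were lower in the IRF8-labelled library by a median log2 ratio of -1.53. If the mix of host cells stayed the same, a lower share of tumour cells would raise the markers of every other cell type alike. However, 7 of 11 lists of immune, fibroblast and endothelial cell types had medians below 0. Their lowest and highest medians, of mast cells and of B and plasma cells, lay 3.87 apart on the log2 scale against summed SDs of 2.82, and without the B and plasma cell list 2.12 apart against 1.26. The mix of host cells can differ between tumours as well, so this gap cannot decide for or against a lower tumour share. A lower share alone would lower genes made only by tumour cells by a common factor. The 22 measured hepatocyte genes had an SD of 3.45 on the log2 scale, with 17 intervals below 0 and 3 above. A common factor would not give that spread. Host liver tissue in the vector-labelled tumour would bring the transcripts most abundant in liver, yet 12 such genes, among them Mup3, Apoc3 and Cyp3a11, had a median of 11.5 counts there (a list chosen after some values had been seen) against 4992 for Fga. A difference in differentiation state between the 2 cell populations, through the construct or through separate selection, may remain as a hypothesis that these 2 libraries do not test.

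Trends on GC content, gene length and expression level did not account for the shifts of chromosomes 9, 16 and 15, whose medians were 0.20, 0.14 and -0.11 after their removal, outside the range of 200 shuffles (-0.045 to 0.051). The smaller offsets of chromosomes 18 and X did not pass these shuffles after the removal. All 35 windows of chromosomes 9, 15 and 16, which were picked for their offsets, were shifted the way of their chromosome. A difference in chromosome copy number between the 2 transduced cell populations could give this. Tumour and host reads were not separated, so a different share of tumour cells with the same altered chromosomes cannot be told apart from it. Such a difference between the populations is a hypothesis, since DNA was not analysed here. If it holds, part of the difference between the libraries may belong to the cell populations and not to IRF8.

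Tex101 and Prr19, both on chromosome 7, were 0 and 2042 and 5 and 238 counts in the vector-labelled and IRF8-labelled library. The 31 measured genes starting within 500 kb of Prr19 had a median log2 ratio of 0.06, with 3 of them at least 2-fold higher and 1 lower.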
